A study of Mus musculus with 16 samples.

How the data were processed

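RNA was measured in eosinophils sorted from the lamina propria of the mouse duodenum, the connective tissue layer under the intestinal epithelium. The 16 libraries form 4 groups of 4: cells with high or low surface CD11c (the integrin alpha chain encoded by Itgax), each collected at zeitgeber time (ZT, hours after lights on) 3 or 15. These times are called AM and PM in the sample titles. Each library came from 1000 sorted cells, whose polyadenylated RNA was reverse-transcribed, amplified and made into Nextera XT libraries, per the labels' protocols. The labels give one total yield for the sequencing as a whole and do not say how it was split over libraries.

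The 2 deposited tables, 1 per CD11c subset, hold the authors' own PM-against-AM comparison and no value of any single library. STAR 2.7.10b, DESeq2 1.38.3 and the genome build GRCm39 are named in the submitters' processing notes, without a role for each. The counting step, the annotation and the method used to shrink fold changes are not given in the sources used here. Per the file headers, each gene has a mean normalised count, a log2 fold change with its standard deviation, and an s-value. The mean normalised count is a signal that the authors deposited as the average over libraries of counts divided by size factors. The log2 fold changes that the authors deposited are shrunken towards 0, because s-values come only from shrunken estimates, and their standard deviations are posterior ones. An s-value is the expected share of wrong signs among genes with an s-value as small or smaller, so it is not a p-value. All deposited s-values lie under 0.05, so the tables list called genes only. A gene that is not listed was either not called or not tested, and its value was not analysed here. How reads shared with near-identical copies were counted is not given in the sources used here, so values of ribosomal protein, class I, Ifitm and immunoglobulin genes are uncertain in that respect. None of the 99 genes in both tables has the same mean normalised count in each, so the tables do not average one common set of normalised libraries.

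The direction (PM over AM) was taken from the tables' names. Positive values therefore mean a higher level at ZT15, and no Per, Cry, Nr1d or Dbp gene, whose phase could check this, is listed. The depth of single libraries is unknown, so no counting interval is given for any gene. Nothing in the labels says that libraries of one group came from separate animals, so the deposited errors measure the spread between these samples, which may be technical. The labels' replicate numbers could not be used, because no column belongs to a library. No coordinates are printed, because the reference given here (GENCODE M21) is of another build than the one in the processing notes. It was used only for transcript GC content and length (the median over a gene's protein-coding transcripts), matched on gene identifiers for 171 of 172 and 1335 of 1340 genes.

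Fixed before the data were examined were the groups, 32 gene lists, the alternatives, the tests and the rule for named genes. That plan assumed an adjusted p under 0.05 as the call. The tables hold s-values instead, so a gene was called at the deposited s-value under 0.05. The named genes are, per subset and among called genes with a mean normalised count of at least 50, the 8 with the largest increase and the 8 with the largest decrease. To these were added the 5 with the smallest s-value in each direction, up to 4 called members of each list, and any listed core clock gene, Itgax, Vipr1, Vipr2 or Nmur1. Predicted genes were counted and not named, and some genes that the rule takes are not reported here by name. Because immunoglobulin segments took 11 of the 16 places by size of change in the CD11c-low table and 3 of 16 in the CD11c-high table, the rule was also run without them, a choice made after seeing the data.

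Computed here, with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, were the following. Calls were counted by direction. For each list with at least 5 called members, higher against lower was compared with the rest of the same table by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists tested in that table (15 for CD11c-low, 1 for CD11c-high). Because only called genes are listed, enrichment of a list among expressed genes and a count adjusted over the list alone could not be computed. For genes in both tables, the share with the same direction was tested against one in 2 by an exact binomial test. The difference of the 2 log2 fold changes was divided by the root of the summed squared standard deviations and tested as a normal deviate, with Benjamini-Hochberg adjustment over the 99 genes. That test treats the subsets as independent, and ignores that both estimates are shrunken. Since an s-value is a running mean, the false sign rate of each gene itself was recovered from successive s-values, and it never decreased down either list. Lists were also compared with 10000 random lists from the same table, each gene drawn among the 30 nearest in GC content, transcript length or both.

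On simulated data, the difference test with the real standard deviations of the 99 shared genes (0.3 in place of those of 1 or more) called 95.3% of genes made to differ by 1.5 in log2 and 0.449% of the others. The simulated values were not shrunken, and smaller differences were not simulated. The largest real difference outside immunoglobulin segments was 0.83, so the power at the differences present is not known. With the directions of the 1340 CD11c-low genes simulated, the list test called 92.5% of lists of 20 made to be lower in 9 of 10 members, and 0.214% of random lists of 10. Alternatives tried were a stricter s-value, minimum fold changes and mean counts, a limit on the standard deviation and correlated errors. Count tests, other size factors, a replicate term and leaving out libraries need values per library and were not run.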

Results

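The libraries compared duodenal eosinophils in the morning (ZT3) and in the evening (ZT15) within 2 sorted subsets, CD11c-high and CD11c-low, with 4 libraries per time and subset. The title of the study places the comparison in how gut neurons and eosinophils control regulatory T cells of the duodenum over the day. Each comparison asked which transcripts of a subset differed between the times. Called genes had mean normalised counts from 11.1 to 16209 (median 418) in the authors' deposited table for CD11c-high cells and from 13.2 to 50146 (median 332) in that for CD11c-low cells. All fold changes below are the authors' shrunken log2 values at ZT15 over ZT3, given with ± their posterior standard deviation.

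In CD11c-low eosinophils, ribosomal protein transcripts fell at ZT15, and Dgat1, Rnf125, Il1r2 and the mitochondrial mRNA mt-Cytb had the smallest s-values among the genes that rose, immunoglobulin segments left out. The clearest increase in the authors' deposited table was that of Dgat1 (ENSMUSG00000022555.13), which encodes the enzyme of the last step of triglyceride synthesis, with a log2 fold change of 0.87 ± 0.11 (s-value 1.0e-15, mean normalised count 5368). Rnf125 (ENSMUSG00000033107.7), a ubiquitin ligase, rose by 1.07 ± 0.17 in the authors' deposited table, and Il1r2 (ENSMUSG00000026073.14), the decoy receptor for interleukin-1, by 1.04 ± 0.18, which are folds of 2.09 and 2.05. Gpr183, an oxysterol receptor that guides immune cell migration, rose by 1.01 ± 0.22, and mt-Cytb by 1.05 ± 0.18 in the authors' deposited table. Among genes with a mean normalised count of at least 50, immunoglobulin segments and predicted genes left out, the largest decreases there were those of Mfsd14b (-1.19 ± 0.24), the pro-apoptotic gene Pmaip1 (ENSMUSG00000024521.9; -1.06 ± 0.24), Anxa11 (-1.03 ± 0.34), the endosomal GTPase gene Rab5a (-1.01 ± 0.21) and the nuclear export receptor gene Xpo1 (s-value 1.24e-07). Kdm6b, which encodes a histone H3K27 demethylase, fell by 0.90 ± 0.21, and Actb, the most abundant listed transcript, fell by 0.82 ± 0.20 in the authors' deposited table.

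The CD11c-low table listed 1340 genes, 700 higher and 640 lower at ZT15. About 67.0 of the 1340 signs are expected to be wrong at the deposited s-values, and 706 genes had a false sign rate of their own under 0.05. Most changes were small. The median log2 fold change in the authors' deposited table was 0.35 among the 692 genes that rose and -0.39 among the 634 that fell, immunoglobulin segments left out. Only 11 of those genes with a mean normalised count of at least 50 changed by 1 or more in log2 in the authors' deposited table, 6 of them higher and 5 lower.

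Ribosomal protein genes had the smallest p of the 15 lists tested in CD11c-low cells. Of 48 called members, 45 fell and 3 rose, against 697 higher and 595 lower in the rest of the table (Fisher's exact test, two-sided, adjusted p = 7.72e-11). Genes of one family are not independent, so this p-value is too small. The ribosomal protein genes with the smallest s-values in the authors' deposited table were Rps12 (-0.94 ± 0.23), Rps21 (-0.72 ± 0.20), Rplp1 (-0.60 ± 0.17) and Rpl32 (-0.65 ± 0.18). Among mitochondrially encoded transcripts, mt-Cytb, mt-Co1 (0.66 ± 0.13), mt-Nd4 (0.65 ± 0.13), mt-Nd2 (0.66 ± 0.18) and mt-Nd1 (0.34 ± 0.12) rose in the authors' deposited table, and the ribosomal RNA mt-Rnr2 fell by 0.27 ± 0.15. This list of 5 higher and 1 lower was not called (Fisher's exact test, adjusted p = 0.662). With 6 members the test had little power, since lists with 8 of 8 higher reached an adjusted p of 0.0404 by the same test. The result therefore does not show that the list matches the rest of the table. The nuclear genes of oxidative phosphorylation were split, with 9 higher, such as Atp5b (0.50 ± 0.15), and 10 lower, such as Ndufb11 (-0.46 ± 0.22), in the authors' deposited table (Fisher's exact test, adjusted p = 1.00). The nuclear RNA Malat1 rose by 0.63 ± 0.15 and the 18S rRNA gene Rn18s-rs5, like Malat1 chosen after its values were seen, fell by 0.76 ± 0.38 in the authors' deposited table. The libraries were made from polyadenylated RNA, so the 18S value is not read as a level of rRNA.

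All 8 called members of the list for the active, CD11c-expressing intestinal eosinophil state rose in CD11c-low cells, and so did all 8 called cAMP-CREB targets (Fisher's exact test, two-sided, adjusted p = 0.0404 for each). Of the active-state list, the authors' deposited table gave Tgm2, which encodes tissue transglutaminase, 0.49 ± 0.12, Clec4a4 0.47 ± 0.15, Hilpda, a lipid droplet gene, 0.51 ± 0.20, Nfkb1 0.35 ± 0.18 and Cd274, which encodes PD-L1, 0.34 ± 0.21. Thbs1 (0.23 ± 0.12) belongs to both lists in the authors' deposited table, along with the rise of Mmp9 (0.24 ± 0.13) and Cd80 (0.20 ± 0.13) in the first. Among the cAMP-CREB targets, Fos, an AP-1 subunit gene, rose by 0.77 ± 0.14, Rgs1 by 0.71 ± 0.19, Rgs2 by 0.60 ± 0.15 and Crem by 0.46 ± 0.22 in the authors' deposited table. Pde4b (0.24 ± 0.14), Nr4a3 (0.38 ± 0.28) and Fosb (0.27 ± 0.23) rose less there, per the authors' deposited table. Both calls were lost when ribosomal protein genes were left out of the rest of the table (adjusted p = 0.0631 for each) and when only genes with a false sign rate of their own under 0.05 were kept (adjusted p = 0.0961 and 0.127). Genes of a list are not independent, so these p-values are too small.

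Inflammatory and eosinophil genes moved in both directions in CD11c-low cells. Of 11 called genes for NF-kB signalling and cytokines, 5 rose and 6 fell (Fisher's exact test, adjusted p = 1.00). Cxcl3 (0.82 ± 0.22), Il1b (0.41 ± 0.15) and Ccl4 (0.31 ± 0.20) rose in the authors' deposited table, whereas Ptgs2 (-0.74 ± 0.23), Rel (-0.51 ± 0.21) and Cxcl2 (-0.24 ± 0.13) fell. Immediate early genes were split 4 and 4 (adjusted p = 1.00 by Fisher's exact test), with Fos (0.77 ± 0.14) and Btg2 (0.31 ± 0.12) higher and Ier5 (-0.59 ± 0.19) and Zfp36 (-0.41 ± 0.15) lower in the authors' deposited table. Fos is also on the cAMP-CREB list, so these 2 lists are not separate results. Of 8 called eosinophil identity genes, 5 rose, including Csf2rb (0.33 ± 0.16), Alox15 (0.26 ± 0.14) and Siglecf (0.23 ± 0.13), and 3 fell, namely Id2 (-0.61 ± 0.30), Adgre1 (-0.29 ± 0.14) and Adgre4 (-0.21 ± 0.16), in the authors' deposited table (adjusted p = 1.00, Fisher's exact test). The antigen presentation list had 6 higher and 4 lower members (adjusted p = 1.00, Fisher's exact test). The class I gene H2-D1 rose by 0.72 ± 0.14 and the class II invariant chain gene Cd74 fell by 0.49 ± 0.33 in the authors' deposited table. Of the leukotriene and prostaglandin list 6 rose, among them Pla2g7 (0.30 ± 0.12) and Lta4h (0.31 ± 0.14), and 2 fell in the authors' deposited table (adjusted p = 0.729, Fisher's exact test). Cholesterol and lipid synthesis genes rose in 5 of 6 cases, with Abcg1 at 0.44 ± 0.22, and Insig1 fell by 0.47 ± 0.24 in the authors' deposited table (adjusted p = 0.662, Fisher's exact test).

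None of the remaining tested lists of the CD11c-low table was called by Fisher's exact test: migration and adhesion had 5 higher and 2 lower members (adjusted p = 0.975), and each of the other 3 had an adjusted p of 1.00. Not being called does not show that a list matches the rest of the table, least of all for the smallest lists. In migration, Itgam (0.57 ± 0.17) and Ccr1 (0.53 ± 0.20) rose and Itgb1 (-0.42 ± 0.24) fell in the authors' deposited table. Actin and cytoskeleton genes were split 6 and 7, with Coro1a (0.33 ± 0.13) higher and Actb, Rhoa (-0.60 ± 0.22) and Arpc3 (-0.79 ± 0.30) lower in the authors' deposited table. Glycolysis and hypoxia genes were split 3 and 3, with Aldoa (0.54 ± 0.17) higher and Slc2a3 (-0.66 ± 0.20) lower in the authors' deposited table. The unfolded protein response had 3 higher members, such as Pdia6 (0.64 ± 0.24), and 2 lower, such as Calr (-0.44 ± 0.25), in the authors' deposited table.

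Lists with fewer than 5 called members were not tested. Of the core clock list, Csnk1e, the casein kinase 1 epsilon gene, rose (0.54 ± 0.15) in the authors' deposited table for CD11c-low cells. In either table, no Per, Cry, Nr1d, Bmal1 or Dbp gene was listed, nor was Itgax, Vipr1, Vipr2 or Nmur1, so their levels were not analysed here. Of receptors for neural signals, P2ry14 rose by 0.16 ± 0.11 in the authors' deposited table. Tgm2, Thbs1 and Ebi3 (0.31 ± 0.20) were the called members of the list of factors that support regulatory T cells, and all 3 rose in the authors' deposited table. The glucocorticoid targets Il1r2 and Cdkn1a (0.68 ± 0.21) rose in the authors' deposited table. So did the chaperone genes Hsp90ab1 (0.64 ± 0.15), Hsp90aa1 (0.24 ± 0.16) and Fkbp4 (0.28 ± 0.24), and the interferon genes Bst2 (0.58 ± 0.31) and Irf1 (0.32 ± 0.19), per the authors' deposited table. Casp1 (0.52 ± 0.29) and Bcl2l11 (0.34 ± 0.19) rose among apoptosis genes while Pmaip1 and Casp9 (-0.40 ± 0.36) fell, in the authors' deposited table. In the cell cycle list, Hmgb2 (0.76 ± 0.22) and Cdkn1a rose while Tubb5 (-0.33 ± 0.19) and Cdkn1b (-0.29 ± 0.25) fell, in the authors' deposited table.

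**Figure D1:**
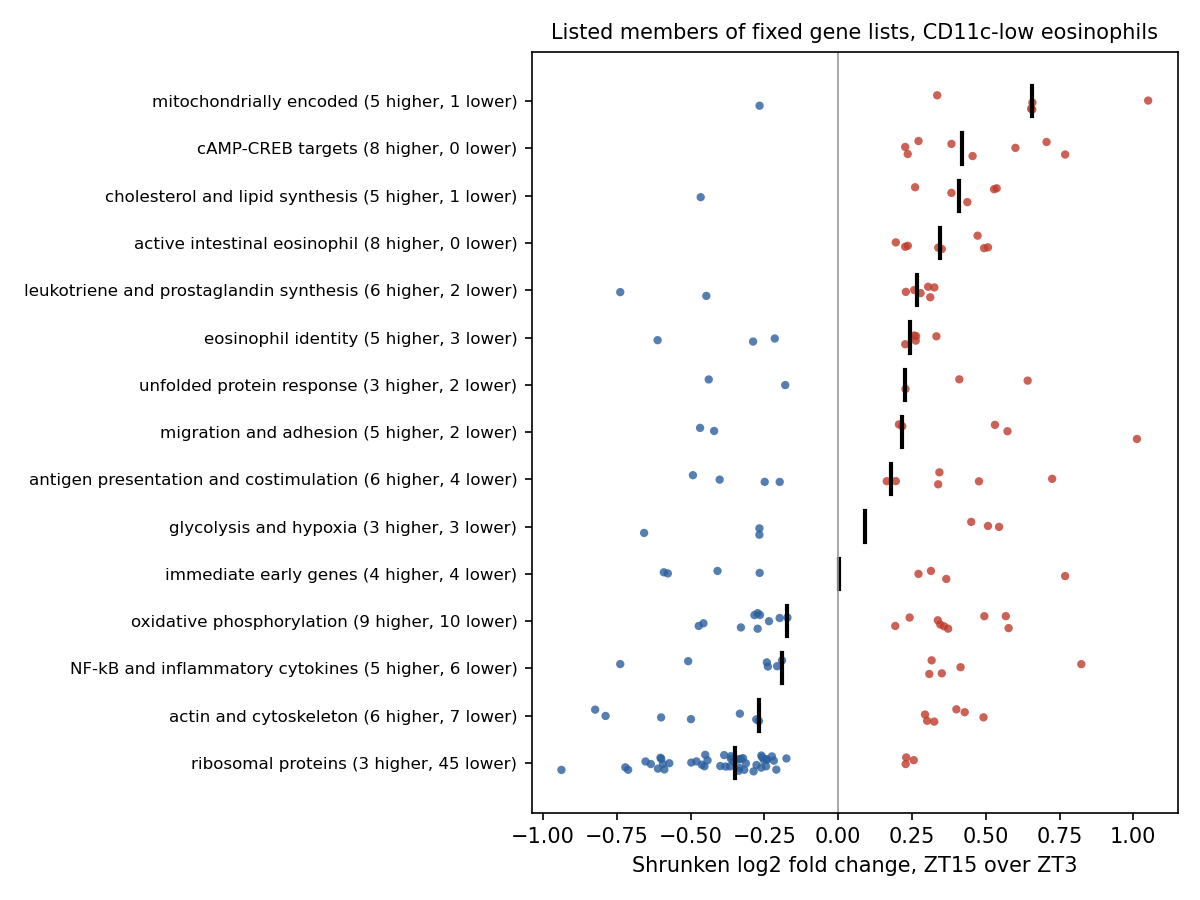
Shrunken log2 fold changes (ZT15 over ZT3, x axis) of the called members of each tested gene list (rows) in CD11c-low eosinophils; each point is a gene, red if higher and blue if lower, and the black bar is the list's median. Ribosomal protein genes lie below 0 in 45 of 48 cases, and the 8 called members of the active eosinophil and cAMP-CREB lists lie above 0.

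Few markers of other cell types were called apart from antibody segments, which says nothing of the level of those not called. In CD11c-low cells, Hdc (histidine decarboxylase, shared by mast cells, basophils and other granulocytes; 0.58 ± 0.20), Bank1 (0.32 ± 0.15) and Ighm (0.24 ± 0.20) rose in the authors' deposited table. Of markers of other myeloid cells and epithelium, Cd68 (0.52 ± 0.30), Cd63 (0.22 ± 0.16) and Trem1 (0.34 ± 0.24) rose, and Cd74 and the keratin gene Krt18 (-0.35 ± 0.24) fell in the authors' deposited table. No called gene came from the lists for stroma, endothelium and nerve, for red cells and platelets or for pancreas enzymes in either table. In CD11c-low cells 14 immunoglobulin variable segments were called, 8 higher and 6 lower, with fitted log2 changes of 20.5 to 26.9 in size in the authors' deposited table. The T and NK cell granzyme gene Gzma was the only other gene beyond 9 in log2, with an s-value of 3.83e-07 at a mean normalised count of 30.4 in the authors' deposited table. No fold is read from fitted values of that size. These segments were called in the same libraries as every gene group above.

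In CD11c-high eosinophils fewer genes were called, 93 higher and 79 lower at ZT15, 172 in all. Outside the immunoglobulin segments and predicted genes, the smallest s-values were those of Laptm4a (ENSMUSG00000020585.6), a lysosomal membrane protein gene that fell by 0.94 ± 0.21 in the authors' deposited table, and those of 2 further genes that fell. These were Arpc3 (ENSMUSG00000029465.15), an actin-nucleating ARP2/3 subunit gene that fell by 1.42 ± 0.35, and Lmnb1, the lamin B1 gene, which fell by 0.59 ± 0.23 in the authors' deposited table. Homer1 (-0.83 ± 0.42), Cops2 (-0.54 ± 0.33), Tmx3 (-0.52 ± 0.30), Dnajb9 (-0.52 ± 0.34), Mrtfa (-0.47 ± 0.33) and Plaur, the urokinase receptor gene (-0.38 ± 0.21), fell as well in the authors' deposited table. The increases were led by H2-T23, a non-classical class I gene (0.83 ± 0.51), Dnase1l3 (0.64 ± 0.35), the cholesterol exporter gene Abcg1 (0.55 ± 0.24), St13 (0.53 ± 0.27) and Jaml (0.50 ± 0.24) in the authors' deposited table. They were followed by Snx20 (0.50 ± 0.27) and Pmvk, an enzyme gene of cholesterol synthesis (0.45 ± 0.25), in the authors' deposited table. Fos rose by 0.41 ± 0.18 in the authors' deposited table for CD11c-high cells.

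Ribosomal protein genes were the one list with at least 5 called members in CD11c-high cells, and all 12 fell, against 93 higher and 67 lower in the rest of the table (Fisher's exact test, two-sided, p = 5.42e-05). Here too the genes are not independent, so the p-value is too small. This call could not be tested at stricter thresholds, since 1 of the 12 had an s-value under 0.01 and 4 had a false sign rate of their own under 0.05. Rplp1 (-0.36 ± 0.21), Rps15a (-0.31 ± 0.23), Rpl22 (-0.29 ± 0.20) and Rps27a (-0.26 ± 0.18) are examples from the authors' deposited table. Of actin and cytoskeleton genes, Arpc3, Tmsb10 (-0.41 ± 0.30) and Pfn1 (-0.19 ± 0.14) fell and Coro1a (0.16 ± 0.12) rose in the authors' deposited table. All 3 called migration genes rose, Gpr183 by 0.26 ± 0.22, Itgb2 by 0.18 ± 0.13 and Ccr1 by 0.17 ± 0.13, in the authors' deposited table. Among the called members of other lists, Xbp1 (0.41 ± 0.35), H2-D1 (0.28 ± 0.18), Bcl2l11 (0.28 ± 0.18), Nfkbie (0.27 ± 0.24) and Ptgs1 (0.26 ± 0.24) rose in the authors' deposited table. So did Gsdme (0.25 ± 0.21), Hdc (0.24 ± 0.19), Hsp90ab1 (0.21 ± 0.17), Il1r2 (0.21 ± 0.15) and Tgm2 (0.18 ± 0.13), per the authors' deposited table for CD11c-high cells. Pmaip1 (-0.29 ± 0.21), Rbm3 (-0.22 ± 0.16) and mt-Rnr2 (-0.20 ± 0.14) fell there, per the authors' deposited table. Of the 172 genes, 9 were immunoglobulin segments, 7 higher and 2 lower, with fitted changes of 9.29 to 24.8 in size in the authors' deposited table. About 8.58 wrong signs are expected among the 172 genes, and 78 genes had a false sign rate of their own under 0.05.

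The third comparison set the subsets side by side. Of the genes called in CD11c-high cells, 99 (57.6%) were also called in CD11c-low cells. Of these, 97 changed in the same direction, 52 higher and 45 lower at ZT15 in both (98.0%, exact binomial test against one in 2, two-sided, p = 1.56e-26, 95% exact interval 92.9 to 99.8%). Genes are not independent, so this p-value is too small, and the labels leave open whether the subsets of a time came from the same mice. How many shared genes chance would give was not computed, since the number of genes tested is not in the tables. The genes with opposite directions were Cdkn2aipnl, at -0.32 ± 0.30 in CD11c-high and 0.23 ± 0.20 in CD11c-low cells in the authors' deposited tables, and the immunoglobulin segment Ighv2-9-1. Genes that rose in both subsets included Dgat1, Pmvk, Abcg1, Fos, H2-D1, H2-T23, Gpr183 and Tgm2, and genes that fell in both included Laptm4a, Arpc3, Homer1, Lmnb1, Pmaip1 and all 12 ribosomal protein genes of the CD11c-high table.

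The change was larger in CD11c-low cells for 79 of the 97 shared genes that were not immunoglobulin segments, with a median ratio of CD11c-high to CD11c-low size of 0.677 and a median ratio of standard deviations of 0.993. Both tables were shrunken, and the amount of shrinkage in each is not known, so this ratio does not measure a difference between subsets. In the test of the difference itself, which uses the same shrunken values, 3 of 99 genes passed after Benjamini-Hochberg adjustment, and 10 had an unadjusted p under 0.05 (two-sided normal test). The shrunken change of Il1r2 was larger by 0.83 ± 0.23 (SE) in CD11c-low than in CD11c-high cells (adjusted p = 0.0182) and that of Rnf125 by 0.83 ± 0.24 (adjusted p = 0.0199). Ighv2-9-1 was the third. Genes that did not pass are not shown to change alike in the subsets. Dgat1, at 0.32 ± 0.17 in CD11c-high and 0.87 ± 0.11 in CD11c-low cells in the authors' deposited tables, did not pass (difference 0.55 ± 0.20, SE, adjusted p = 0.146), although it did (adjusted p = 0.0300) when the errors of the subsets were taken to have a correlation of 0.3. Genes called in 1 table alone could not be tested this way, so the larger number of calls in CD11c-low cells is not shown to be a difference between the subsets.

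**Figure D2:**
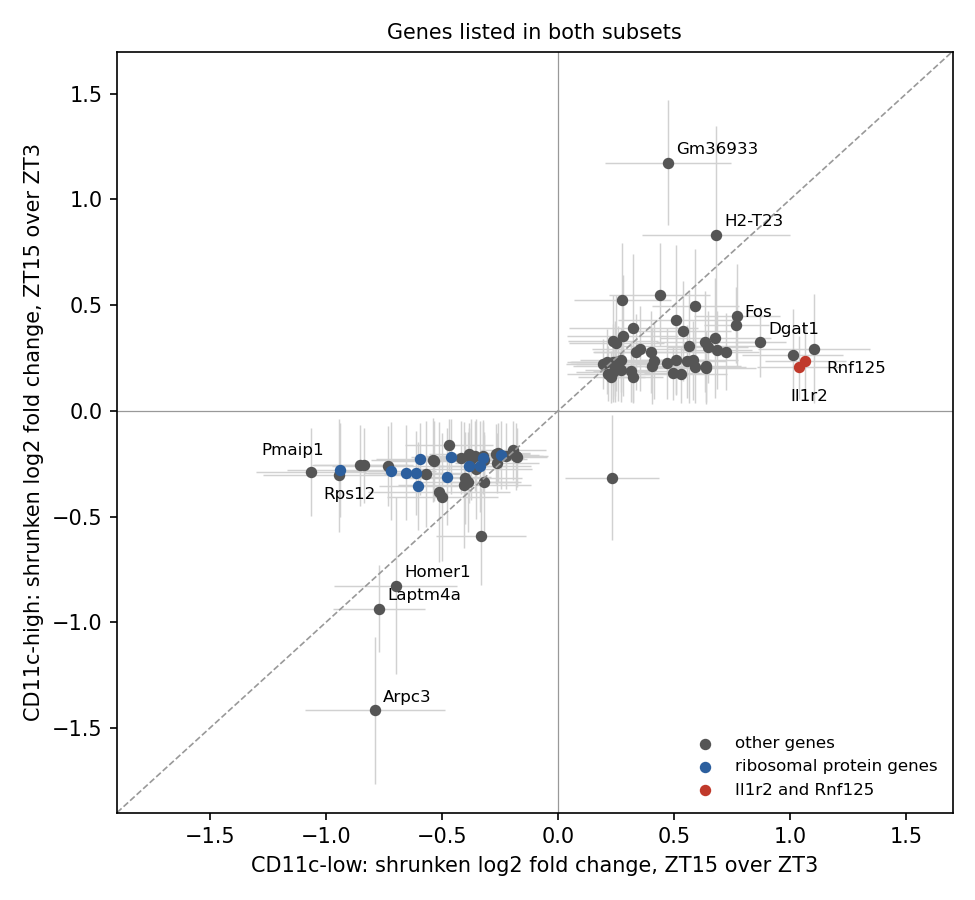
Shrunken log2 fold changes (ZT15 over ZT3) of the 97 genes called in both subsets, immunoglobulin segments left out, in CD11c-low (x axis) and CD11c-high (y axis) eosinophils; blue points are ribosomal protein genes, bars are posterior standard deviations and the dashed line marks equal change. All but 1 gene lie in the quadrants of equal sign, and Il1r2 and Rnf125 (red) lie farthest below the line relative to their errors among genes that rose.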

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

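The tests in this part were chosen after the results were seen, except the test of the difference between subsets, which was fixed before. Il1r2 and Rnf125 were flagged because their shrunken log2 fold changes differed between the subsets (adjusted p = 0.0182 and 0.0199, normal test of the difference over 99 genes). Each table was shrunken by an unknown amount, so unequal shrinkage is not excluded as a part of these differences. Il1r2 had a log2 fold change of 0.21 ± 0.15 in CD11c-high and 1.04 ± 0.18 in CD11c-low cells, and Rnf125 of 0.24 ± 0.17 and 1.07 ± 0.17, in the authors' deposited tables.

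Ighv2-9-1 was flagged for opposite directions, with a fitted log2 value of 21.1 ± 3.3 in CD11c-high and -26.4 ± 3.3 in CD11c-low cells in the authors' deposited tables (adjusted p = 5.40e-22). It is 1 of 9 immunoglobulin segments of the CD11c-high and 14 of the CD11c-low table with fitted changes beyond 9 in log2. One shift in the amount of B-lineage RNA between AM and PM would move the segments one way, but 6 of the 14 CD11c-low segments (42.9%, 95% exact interval 17.7 to 71.1%) went against the others, which argues against it as the whole cause. Although eosinophils were sorted, clones of antibody-producing cells that differ between libraries may put one segment in few libraries. If the clones also differed between CD11c-high and CD11c-low libraries, most segments would not recur. Only 1 of the 9 CD11c-high segments (11.1%) recurred in the CD11c-low table in the same direction. If the subsets of a time came from the same mice, which is not known, shared clones could make segments recur. A segment that is not listed was also only not called or not tested, so the count does not decide the question. The hypothesis was written after these values were seen, and the 9 include Ighv2-9-1, so the count is not an independent test of it. A time-of-day difference in which clones are present stays open as well, since values per library would be needed to see how many libraries carry each segment.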

How the results depend on the processing

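No paired analysis was possible because the deposited tables hold no value of a single library; for the same reason leaving out libraries, count tests, other size factors and regroupings of the samples were not run, and an s-value under 0.1 added no genes, since none above 0.05 is listed. The largest changes came with stricter thresholds, which by construction keep fewer genes. With an s-value under 0.01, 38 CD11c-high and 518 CD11c-low genes remained; with the gene's own false sign rate under 0.05 (added after seeing the data), 78 and 706; and with an absolute log2 fold change of at least 1, 13 and 30. Genes called in both subsets numbered 15, 35 and 2 under these settings, of which 14, 34 and 1 had the same direction. The last 2 were the immunoglobulin segments Ighv8-5 and Ighv2-9-1, so that setting leaves no other gene in which to compare directions. Immunoglobulin segments left out, 4 of the 13 CD11c-high and 16 of the 30 CD11c-low genes remained at a log2 fold change of at least 1. In CD11c-low cells the number of one-sided lists fell from 3 to 1 (ribosomal proteins) both at an s-value under 0.01, where the active eosinophil and cAMP-CREB lists had fewer than 5 called members, and at an own rate under 0.05. In CD11c-high cells the ribosomal protein list, the 1 list called there, could be tested under neither, with 1 and 4 of its 12 members left; in neither subset could a list be tested at a log2 fold change of at least 1. Minimum mean normalised counts of 10 or 100, a standard deviation of at most 1.5 and leaving out immunoglobulin segments kept the number of called genes in each subset within 1.5 times its main value. For genes called in both subsets and for the difference test, only the minimum of 100 and leaving out immunoglobulin segments were run of these, and for the lists only the minimum of 100; these counts also stayed within 1.5 times. The difference test called 2 to 4 genes over its alternatives. Of the named genes, 78 of 101 in CD11c-low and 22 of 45 in CD11c-high cells stayed called at an s-value under 0.01. Depth could not be weighed, because counts per library are not in these tables.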

Other observations

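The gene families in this paragraph and the next were chosen after the data were seen, and 9 of the 14 had at least 5 called CD11c-low members and were tested; none passed Fisher's exact test with Benjamini-Hochberg adjustment. RNA splicing factors of the SR and hnRNP type came nearest, with 13 of 16 lower at ZT15 in CD11c-low cells (unadjusted p = 0.00971, adjusted p = 0.0874), among them Ptbp3 (-0.76), U2af2 (-0.67) and Hnrnpu (-0.53) in the authors' deposited table, while Srsf7 (0.60) was higher. In CD11c-high cells all 4 called members, Srsf5, Srsf6, Tra2a and Sfpq, were lower. Of protein phosphatase subunit genes, 9 of 12 fell in CD11c-low cells (Fisher's exact test, adjusted p = 0.240), including Ppm1a (-0.82), the calcineurin genes Ppp3r1 (-0.60) and Ppp3ca (-0.43), and Ppp6c (-0.57) in the authors' deposited table. Proteasome genes went the other way, with 7 of 8 higher (Fisher's exact test, adjusted p = 0.240), such as Psmd12 (0.46) and Adrm1 (0.44) in the authors' deposited table.

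The 5 families with fewer than 5 called CD11c-low members were not tested, and every called member of these 5 was higher at ZT15. Examples from the authors' deposited table are Ifitm3 (0.53), Ifitm1 (0.40) and Ifitm2 (0.24), and Cd300ld (0.58), Cd300lf (0.50) and Cd300c2 (0.36). The receptor chains for interferon gamma went apart, Ifngr1 at 0.83 ± 0.15 and Ifngr2 at -0.39 in the authors' deposited table. The 4 called class I genes are another of these families, with H2-T23 at 0.68, H2-T24 at 0.37 and B2m at 0.16 beside H2-D1, and so are Rgs14 (0.44), Rgs1 and Rgs2, in the authors' deposited table. Jak2 (0.52), Stat3 (0.34) and Jak1 (0.24) rose there, per the authors' deposited table. Lysosomal hydrolase genes were 11 higher, with Gusb at 0.71, and 5 lower, with Manba at -0.58, in the authors' deposited table (Fisher's exact test, adjusted p = 0.387). The subunits of ARP2/3 were 5 lower and 2 higher (adjusted p = 0.403, Fisher's exact test), the 2 being the alternative subunits Arpc1a and Arpc1b. The Rab GTPase, vacuolar ATPase, cytokine receptor and translation factor families had adjusted p-values of 0.417, 0.424, 0.387 and 0.792.

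The fall of ribosomal protein genes was set against sequence properties with tests chosen after the result was seen. Their median GC content was 51.7% and that of other CD11c-low genes 49.1%, and their median transcript length 642 against 2040 bases. Of those called in CD11c-low cells, 93.8% were lower, whereas the highest share among 10000 random lists was 62.5% when matched on GC content and 68.8% when matched on transcript length, which argues against either property as the whole cause. In the CD11c-high table the decrease of all 12 had a two-sided p of 0.0004 against random lists matched on both. The highest share lower among those lists was 100%, equal to the observed share. The 12 CD11c-high genes thus did not exceed every matched list, as those of CD11c-low cells did. The labels of 0 libraries give a batch or date, so a batch that coincides with the time of day cannot be told apart from the time itself.

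Direction also went with GC content. Without ribosomal, mitochondrial and immunoglobulin genes, 27.4% of the 212 CD11c-low genes of lowest GC content (up to 42.9%) were higher at ZT15 (95% exact interval 21.5 to 33.9%), against 68.2% of the 211 of highest GC content (61.5 to 74.5%), and the rank correlation across genes between log2 fold change and GC content was 0.234, where genes are not independent replicates and only called genes enter. Keeping ribosomal and mitochondrial genes gave 0.204, and with mean count and transcript length held constant (a test set before its result was seen) it was 0.185, which argues against each as the whole source. In CD11c-high cells the correlation was 0.182 over 149 genes. GC-dependent amplification or capture that differed between the AM and PM libraries may give such a trend, and so may a daily change in genes that differ in GC content; these cannot be told apart without values per library.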
